A study of Mus musculus with 2 samples.

How the data were processed

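LXRα ChIP-seq was analysed from 2 libraries of bone marrow-derived macrophages of LXRβ knockout mice, 1 from cells treated with GW3965 and 1 from cells treated with GW3965 + LPS. Group, dose and time were taken from the treatment labels. The dose of LPS is given there in nM, a unit not usual for LPS, and is printed as labelled. Per the labels' protocols, bone marrow cells were differentiated in medium conditioned by cells that express M-CSF, crosslinked with disuccinimidyl glutarate and formaldehyde and sonicated. Libraries were amplified by PCR without stated molecular identifiers, so tags are not all independent molecules.

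The submitters' processing notes name CASAVA 1.8.4, Bowtie2 2.2.9 and HOMER 4.9, and the build mm10. Per the file headers, the authors called peaks in each library separately with HOMER findPeaks in its transcription factor mode, against an input library of the same name for both. The headers require 4-fold over input, 4-fold over the surrounding 10 kb, a Poisson p of 1e-04 and an FDR of 0.001, and consider at most 1 tag per bp. Peaks are 151 bp wide in the GW3965 list and 147 bp in the GW3965 + LPS list. Per the file headers, 17420 of 86818 putative GW3965 peaks and 16993 of 71893 putative GW3965 + LPS peaks were removed by the input requirement, and 14449 and 10443 by the local one. Read trimming and the handling of duplicates before peak calling are not given in the sources used here.

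The deposited lists give several values per peak. The normalised tag signal is, per the file headers, the authors' tag count in the peak scaled to 10000000 tags per library, called normalised tags here. The deposited total tags are whole-number counts. For 10.8% of GW3965 peaks and 0.0% of GW3965 + LPS peaks they differed by over 1% from the normalised value scaled back to the library. The normalised values were therefore used for all ratios. Counting intervals of single peaks used the deposited total tags, so at those GW3965 peaks an interval need not centre on its ratio. The authors' findPeaks score counts tags with at most 1 per bp, so it levels off at tall peaks (highest 301 and 287), and it was used to rank peaks within a list. Score ratios between libraries served only as an added alternative to the tag ratio, since the score is itself a tag number. The deposited control tag signal is the input in the peak scaled to the library. The authors' fold ratios over input, over the local region and for clonal tags were used to describe and filter peaks within a list. The deposited focus ratio, a fraction, and the authors' p-value columns were not used.

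Peaks on chromosomes 1 to 19, X and Y were kept, which left out 9 GW3965 and 7 GW3965 + LPS peaks. Peaks of both lists were matched by an overlap of at least 1 bp. Shared peaks were paired one to one, and the log2 ratio of normalised tags was taken without a pseudocount. Intervals are exact Clopper-Pearson for shares, exact conditional binomial for the tag ratio of a peak, and from order statistics for medians. The median number of tags per peak was 28 and 26. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.

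Genes came from a RefSeq table of the GRCm38.p6 assembly (mm10 coordinates) with 21887 protein-coding genes. The table gives spans without strand, exons or introns. The planned assignment to the nearest transcription start was therefore replaced by the nearest gene body within 50 kb, and the planned window around starts by 1 kb around either end of a gene. The planned motif shares need genome sequence and were not run here. The 13 gene lists held 266 entries, of which 263 matched a symbol in the table. They covered LXR targets, NF-kB and inflammatory genes, interferon response, macrophage identity, cholesterol synthesis and uptake, lysosome and phagocytosis, glycolysis and hypoxia, alternative activation, markers of neutrophils, lymphocytes and dendritic cells, hepatocyte genes, and genes of silent lineages. Each list's median log2 ratio at shared peaks was placed among 10000 random sets of shared peaks of the same size, matched on decile of mean tag count, as a description of these libraries. A second percentile, added after the data were seen, was matched on distance to the nearest gene end too.

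The lists, the comparisons, the rule for named genes and the alternatives, apart from those marked as added later, were set before the data were examined. The rule names 14 genes throughout (Abca1, Abcg1, Srebf1, Mylip, Lpcat3, Scd2, Apoe, Nr1h3, Tnf, Il1b, Nfkbia, Ptgs2, Nos2 and Irf1). It adds up to 4 genes per list whose assigned peak has the highest mean tag count. It also adds the genes within 50 kb of the 6 highest-scoring peaks without a counterpart per library, and of the 6 shared peaks with the highest and the 6 with the lowest ratio among those with 50 or more normalised tags in the higher library. Other genes named were chosen after their values were seen: Ifnb1 and Smpdl3a, for their weight in a list, and those identified as such in the closing section.

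Matching and intervals were tested on simulated data. For 54934 peaks of the GW3965 list with a known matched share of 60.0%, matching returned 60.0%. The copies were moved by up to 60 bp, less than a peak width, so they overlapped by construction. Tag counts were simulated with counting error only. These runs check the code, not how well separately called lists match or how duplicated tags affect intervals. Tag ratio intervals at the depth of these libraries held the true ratio for 96.1% of 30000 simulated peaks, and 200 peaks simulated at a log2 ratio of -0.50 had a median of -0.47. Alternatives covered the overlap rule, list length, peak score and fold filters, chromosomes, pseudocount, tag measure, window and gene assignment.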

Results

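LXRα is a nuclear receptor that binds oxysterols and drives genes of cholesterol efflux and fatty acid synthesis. Its binding sites were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse macrophages grown from bone marrow of animals that lack LXRβ, the paralog of LXRα. One library came from cells given GW3965, a synthetic LXR agonist, at 1 µM for 24 h. The other came from cells given GW3965 at the same dose together with lipopolysaccharide (LPS), the bacterial outer membrane component sensed by Toll-like receptor 4, at a dose labelled 100 nM, for 24 h. The pair addresses how the LXRα binding pattern under agonist differs when the cells also receive LPS. The GW3965 library held 27935683 mapped tags and the GW3965 + LPS library 27202702. With 1 library per group no difference had a replicate check, no test across conditions was run, and each difference given here compares these 2 libraries. All intervals are 95% intervals unless stated otherwise, and none covers variation between replicate libraries. Those of shares and of single peaks cover counting error only. Those of medians come from the spread across peaks, taken as independent of each other. Peak scores and folds over input are those of the authors' peak caller. The peak lists carry no measure of the Nr1h2 product LXRβ, so the genotype in the labels was not checked here.

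The peaks with the most tags near LXR target genes were those of lipid synthesis and cholesterol efflux genes, and most of them held similar tag counts in both libraries. The tallest peak of the target list lay 9426 bp from Scd2, which encodes a stearoyl-CoA desaturase, at chromosome 19, 44284175 to 44284325 (mm10). It held 639 normalised tags (scaled to 10000000 tags per library) with GW3965 and 695 with GW3965 + LPS, a log2 ratio of 0.12 (0.023 to 0.21). A peak inside Srebf1, the gene of the lipogenic transcription factor SREBP-1 (chromosome 11, 60210544 to 60210694), held 359.8 and 373 normalised tags, a log2 ratio of 0.052 (-0.083 to 0.17). The strongest peak of Abca1, the transporter that passes cholesterol to apolipoprotein A-I, overlapped one end of the gene (chromosome 4, 53159865 to 53160015) and held 305 and 295 normalised tags, a log2 ratio of -0.047 (-0.19 to 0.094). Lpcat3, which encodes a phospholipid-remodelling acyltransferase, had a peak 379 bp from the gene with 164.7 and 183 normalised tags, a log2 ratio of 0.16 (-0.030 to 0.34). Peaks near Scd1 and the fatty acid elongase gene Elovl5 held more tags with LPS, at log2 ratios of 0.22 (0.092 to 0.33) and 0.28 (0.15 to 0.42).

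At Mylip, Abcg1 and Nr1h3 the strongest shared peak held fewer tags with LPS. The main peak of Mylip, whose product marks the LDL receptor for degradation, lay inside the gene (chromosome 13, 45391622 to 45391772). It held 220.5 normalised tags with GW3965 and 136 with GW3965 + LPS, which is 0.615-fold (log2 -0.70, -0.90 to -0.52). The shared peak inside Abcg1, a transporter that passes cholesterol to HDL (chromosome 17, 31058796 to 31058946), held 172 and 125 normalised tags, which is 0.726-fold (log2 -0.46, -0.67 to -0.26). The 3 other shared Abcg1 peaks held more tags with LPS, with intervals that include no difference; the tallest of them had 86.6 and 94.8 (log2 0.13, -0.14 to 0.38). Weaker Abca1 peaks went both ways: one inside the gene held 58.0 and 32.7 normalised tags (log2 -0.83, -1.23 to -0.46), and one 27370 bp away held 23.6 and 40.4 (log2 0.78, 0.32 to 1.24). Nr1h3, which encodes LXRα itself, had a peak inside the gene with 27.2 and 16.2 normalised tags (log2 -0.75, -1.32 to -0.20). Apoe had 1 peak in each library, with 5.73 and 8.46 normalised tags, and the interval of its log2 ratio of 0.56 ran from -0.42 to 1.58. At Abca1, 14 peaks were called with GW3965 and 8 with GW3965 + LPS, of which 7 overlapped. At Abcg1, 8 and 7 were called and 4 overlapped. The control library also held tags at the strongest of these sites. The median was 88.4 scaled control tags over the 18 target list peaks of score 100 or more. At that score it was 22.0 over other peaks within 1 kb of a gene end and 16.8 over those over 10 kb away. The median LXRα tags of these other peaks were lower as well, at 176 and 146 against 471.5 over the 18. Over all GW3965 peaks, of any score, the median was 3.2 control tags.

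**Figure D1:**
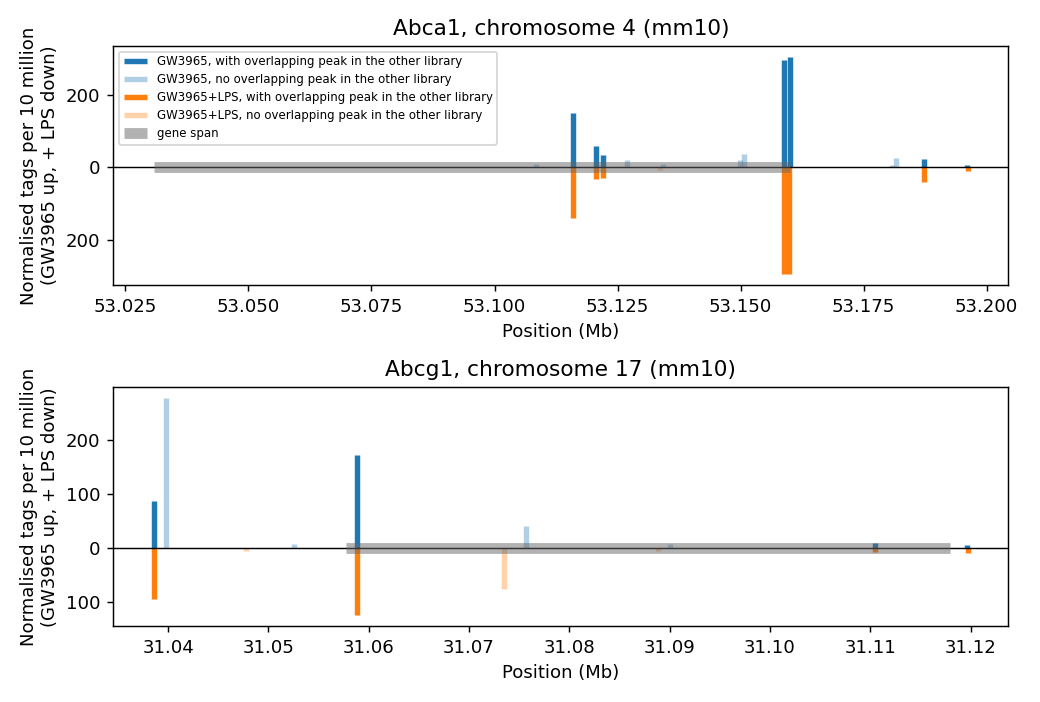
LXRα peaks assigned to Abca1 (top) and Abcg1 (bottom), with position on the chromosome in megabases (mm10) on the horizontal axis and normalised tags on the vertical axis, upward for GW3965 and downward for GW3965 + LPS. Each bar is 1 peak of a single library, pale bars have no overlapping peak in the other library and the grey bar is the gene span; at Abca1 the tallest bars reach 305 and 295, and at Abcg1 the tallest GW3965 bar, 278, is pale.

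Fewer LXRα peaks were called in the library with LPS, and the peaks found in it lay more often near gene ends. The GW3965 library had 54934 peaks on the standard chromosomes and the GW3965 + LPS library 44437. Of the GW3965 peaks, 31258 (56.9%, 56.5 to 57.3) overlapped a GW3965 + LPS peak, and 31256 (70.3%, 69.9 to 70.8) of the GW3965 + LPS peaks overlapped a GW3965 peak. After peaks were moved by 5 kb, 1.56% and 1.94% overlapped. Overlap depended on peak score: it was 29.9% in the lowest and 77.7% in the highest score decile of GW3965 peaks, and 38.4% and 96.5% for GW3965 + LPS peaks. Peaks within 1 kb of an end of a protein-coding gene made up 19.2% (18.9 to 19.6) of the GW3965 list and 25.0% (24.6 to 25.4) of the GW3965 + LPS list. In numbers these were 10569 and 11094 peaks, while peaks over 10 kb from any gene end numbered 29436 and 21206. Among peaks called in a single library, 14.2% (13.7 to 14.6) of the GW3965 ones and 29.5% (28.7 to 30.3) of the GW3965 + LPS ones lay in that window. Conversely, 59.1% of peaks found with GW3965 alone and 43.8% of those found with GW3965 + LPS alone lay over 10 kb from any gene end. Peaks inside a gene span were 58.4% and 59.5% of the lists. The immunoprecipitates differed in efficiency, with 7.13% and 5.29% of tags in peaks per the file headers. A region without a called peak still has tags, which the peak lists do not give, so a peak in 1 list alone is not a site bound in 1 condition alone.

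**Figure D2:**
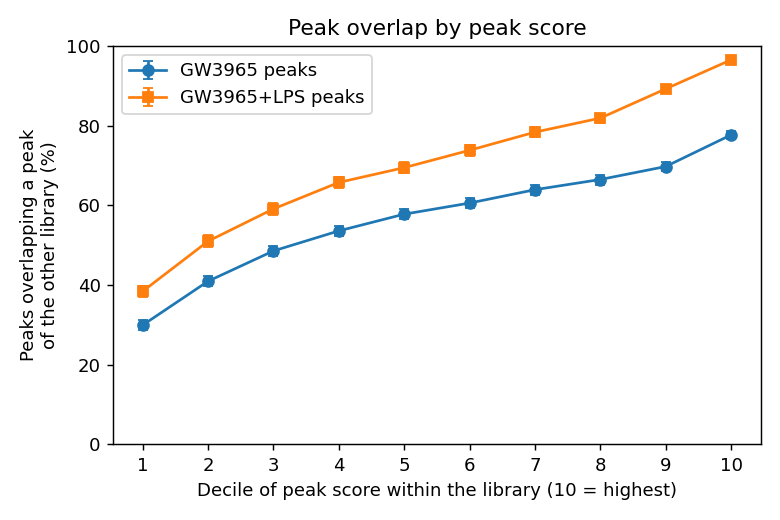
Percentage of LXRα peaks that overlapped a peak of the other library (vertical axis) in each decile of peak score within a library (horizontal axis), with exact binomial 95% intervals as error bars. Overlap runs from 29.9% to 77.7% for GW3965 peaks and from 38.4% to 96.5% for GW3965 + LPS peaks.

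At sites bound in both libraries, LXRα tags were slightly lower with LPS over 10 kb from gene ends and about level near them. Over 31256 peaks paired one to one, the median log2 ratio of GW3965 + LPS over GW3965 was -0.076 (-0.081 to -0.069), or 0.948-fold. Of them, 17583 held fewer normalised tags with LPS, 1534 were at or below 0.5-fold and 267 at or above 2-fold. The SD of the log2 ratio was 0.50, against 0.39 from counting alone. It was 0.36 against 0.54 in the lowest decile of mean tag count and 0.43 against 0.22 in the highest. Pairing requires a called peak in both libraries, which leaves out large differences at weak peaks. At peaks of any height it leaves out falls that take a peak under 4-fold over input. Peaks within 1 kb of a gene end had a median log2 ratio of 0.040 (0.038 to 0.042, 7209 peaks), and peaks over 10 kb away had -0.16 (-0.17 to -0.15, 15437 peaks). In the highest decile of mean tag count the median was -0.24 (-0.25 to -0.22). Among gene-end peaks over 15 normalised tags the median was 0.0086 (-0.016 to 0.035, 1781 peaks), and equal raw tag counts would give 0.038.

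Interferon response genes had a low tag ratio at shared peaks. They also had the highest share of peaks called with GW3965 + LPS alone among the 13 gene lists, a rank that rested on Irf1. Their 32 shared peaks had a median log2 ratio of -0.46 (-0.76 to -0.042), or 0.726-fold, and 24 of the 32 held fewer tags with LPS. That median was at percentile 0.02 of 10000 random sets of shared peaks of the same size and tag count, and below all sets matched on distance to gene ends as well. Of the 97 peaks of the list in either library, 28 (28.9%, 20.1 to 39.0) were called with GW3965 + LPS alone, against 19.4% of all peaks, and 37 with GW3965 alone. The 19.4% is not matched on distance to gene ends. Over all genes, 29.5% of peaks called with GW3965 + LPS alone lay within 1 kb of a gene end, against 14.2% with GW3965 alone. Part of the higher share can therefore come from location. Of 27 members, 21 had a peak with GW3965 and 20 with GW3965 + LPS. The peak 3891 bp from Rsad2, which encodes the antiviral enzyme viperin, held 39.4 and 20.6 normalised tags (log2 -0.94, -1.45 to -0.49), while the gene had 2 peaks with GW3965 and 5 with GW3965 + LPS, 4 of the latter without a counterpart. The peak 36 bp from Gbp2, an interferon-inducible GTPase gene, held 36.5 and 16.5 (log2 -1.15, -1.70 to -0.64). Socs1, a feedback inhibitor of cytokine signalling, was at 25.4 and 21.7 normalised tags (log2 -0.23, -0.75 to 0.29). Irf1, a transcription factor of the same response, had 5 peaks with GW3965 and 11 with GW3965 + LPS, 8 of the latter without a counterpart. Its strongest shared peak held 24.3 and 25.0 normalised tags. Irf1 and Rsad2 thus gave 8 and 4 of the 28 peaks called with GW3965 + LPS alone. The next highest share among the lists was 25.7%, for glycolysis and hypoxia genes. Without the peaks of Irf1 the share of the interferon list would fall below this value, so its rank rested on that gene. Without the peaks of Rsad2 alone it would stay above. Leaving out Ifnb1, the interferon beta gene, with 4 shared peaks moved the list median to -0.26, level with the neutrophil marker list, and its percentile to 5.62. Without any other single gene the percentile was at most 0.515.

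LXR target genes stood high against matched peaks, with a median near no difference. Of the 28 list members, 24 had a peak with GW3965 and 25 with GW3965 + LPS. Their 73 shared peaks had a median log2 ratio of -0.013 (-0.20 to 0.12), of which 38 were lower with LPS. The median of the matched random sets was -0.14, and the list lay at percentile 98.1, or 98.7 with distance to gene ends matched as well. This position rested on few genes: leaving out each of 23 genes in turn gave percentiles from 92.2, without Scd2, to 99.8, without Smpdl3a, and 9 of the 23 omissions put the list within the central 95% of random sets. In the matched sets of both lists the peaks of 1 gene were not kept together, so percentiles treat neighbouring peaks as separate.

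NF-kB and inflammatory genes lay within the central 95% of matched random sets. All 31 members had a peak with GW3965 and 30 with GW3965 + LPS, and 68 of their 94 shared peaks were lower with LPS. Their median log2 ratio was -0.22 (-0.36 to -0.16), at percentile 7.71. Single sites went both ways. A peak inside Nfkbia, which encodes the NF-kB inhibitor IκBα (chromosome 12, 55491820 to 55491970), held 88.1 and 109.9 normalised tags (log2 0.32, 0.072 to 0.57), while the gene's 7 shared peaks had a median log2 ratio of -0.35 and the one 540 bp from it held 42.6 and 33.5 (log2 -0.35, -0.79 to 0.019). The peak at the end of Tnf had 19.7 and 25.4 (log2 0.37, -0.17 to 0.90). A peak 12723 bp from the chemokine gene Ccl2 had 78.4 and 52.2 (log2 -0.59, -0.91 to -0.29), and one 9715 bp from Acod1, the itaconate-producing enzyme gene, had 54.1 and 46.3 (log2 -0.22, -0.58 to 0.13). At Il1b, 10 and 9 peaks were called and 7 overlapped, and the peak 2354 bp from the gene held 34.4 and 16.2 normalised tags (log2 -1.09, -1.64 to -0.56) and the one 4257 bp from it 25.1 and 30.1 (log2 0.26, -0.23 to 0.73). Nos2, the inducible nitric oxide synthase gene, had 5 peaks with GW3965 and 1 with GW3965 + LPS. Ptgs2, which encodes cyclooxygenase 2, had 3 and 1.

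The other 10 lists lay within the central 95% of matched random sets. Macrophage identity genes had a median log2 ratio of -0.18 over 98 shared peaks (percentile 29.7), with the strongest shared peaks near the transcription factor gene Irf8 (102 and 89.3 normalised tags) and in the chemokine receptor gene Cx3cr1 (81.3 and 68.7). Lysosome and phagocytosis genes had -0.18 over 83 peaks (percentile 26.5), glycolysis and hypoxia genes -0.17 over 57 (percentile 19.2), and alternative activation genes -0.12 over 38 (percentile 50.5). The strongest shared peaks of these groups lay in Tfeb (72.7 and 61 normalised tags), a regulator of lysosomal genes, in the hexokinase gene Hk2 (46.9 and 44.5) and near Tgfb1 (62.6 and 74.3). Cholesterol synthesis and uptake genes had -0.022 over 34 peaks (percentile 67.1), and the strongest shared peak, near the LDL receptor gene Ldlr, held 21.5 and 18.7 normalised tags. For markers of other blood cells the medians were -0.26 over 12 neutrophil marker peaks (percentile 24.4), 0.052 over 16 lymphocyte marker peaks (percentile 81.5) and -0.028 over 34 dendritic cell marker peaks (percentile 69.6). The neutrophil collagenase gene Mmp8 had the tallest shared neutrophil marker peak, at 55.1 and 26.1 normalised tags (log2 -1.08, -1.51 to -0.67). Hepatocyte genes had -0.17 over 8 peaks (percentile 21.1). Among 20 genes of silent lineages, 5 had a peak with GW3965 and 5 with GW3965 + LPS, 4 of them in both libraries, and the 5 shared peaks had a median of 0.14 (percentile 70.9) at a median of 6.80 normalised tags with GW3965.

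**Figure D3:**
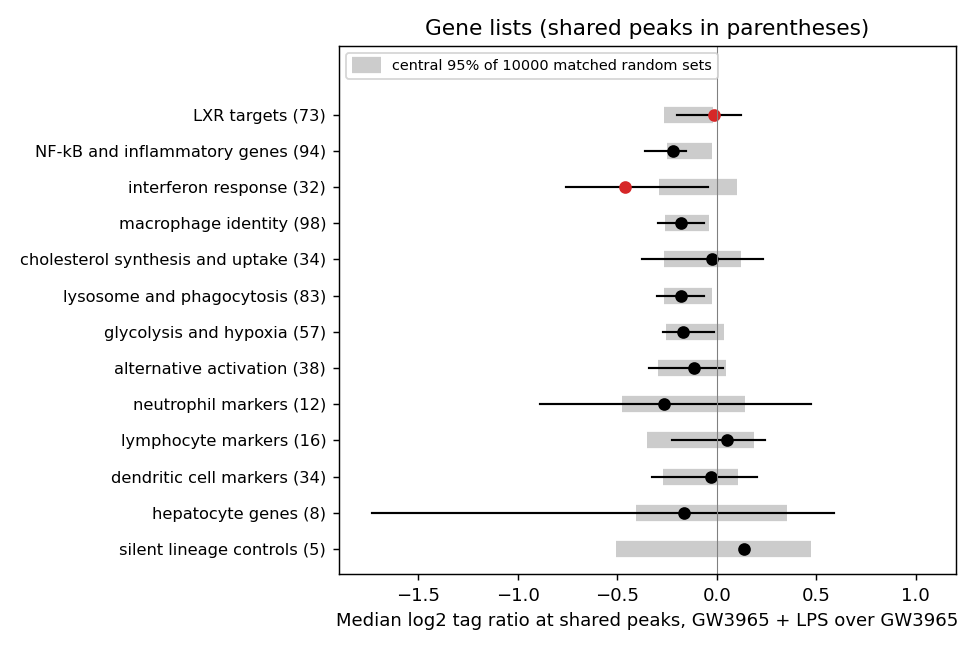
Median log2 ratio of normalised tags, GW3965 + LPS over GW3965, at shared LXRα peaks of each gene list (horizontal axis), with the number of shared peaks in parentheses and 95% intervals of the median as lines where the number of peaks allows one. Grey bars hold the central 95% of 10000 matched random sets, and the points outside them, in red, are interferon response genes at -0.46 and LXR targets at -0.013.

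**Figure D4:**
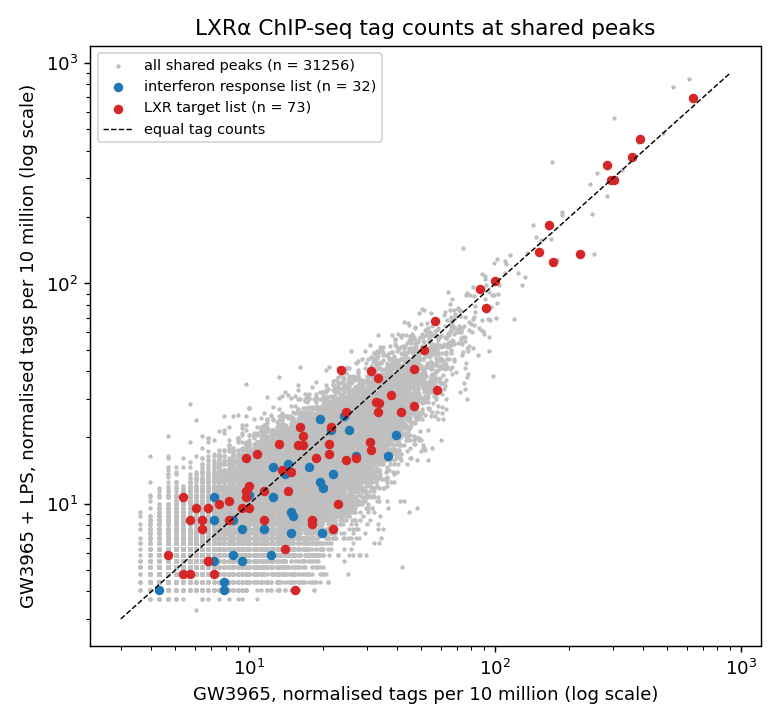
Normalised tags at each of 31256 shared LXRα peaks with GW3965 (horizontal, log scale) and GW3965 + LPS (vertical, log scale), in grey, with the 73 peaks of the LXR target list in red, the 32 of the interferon response list in blue and equal counts as a dashed line. The tallest LXR target peaks lie close to the line, up to 639 and 695 near Scd2, and Mylip, at 220.5 and 136, lies below it.

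The strongest peaks called with GW3965 alone included an Abcg1 site. This peak, 17930 bp from the gene (chromosome 17, 31039689 to 31039839), held 278 normalised tags. It stood beside a peak 25247 bp from the chemokine receptor gene Ccr1 (390.2 normalised tags) and peaks in Asph (138) and Eepd1 (107), the latter an LXR-responsive gene. Peaks near Pmaip1 (95.2) and in Bcl2l1 (96.7), which encode proteins that promote and oppose apoptosis, completed the 6 of highest score within 50 kb of a gene. The peak caller required 4-fold over input, and these 6 peaks were 4.22-fold (Ccr1) to 7.21-fold (Bcl2l1) over it. A tag count lower by 5.21% at Ccr1 or by 18% at Abcg1 would have put the peak under that limit. With GW3965 + LPS alone, the 6 of highest score lay in Cdk8 (735 normalised tags), Filip1l (698), Lars2 (479), Zc3h7a (347), the retinoic acid-degrading enzyme gene Cyp26b1 (129) and Abcg1 (75.4, chromosome 17, 31073414 to 31073560). These 6 peaks were 4.99-fold (Zc3h7a) to 8.99-fold (Lars2) over input. A tag count lower by 19.8% at Zc3h7a or by 21.3% at Cyp26b1 would have put the peak under the limit. The scaled control tags at Cdk8, Filip1l, Zc3h7a and Lars2 were 308, 323, 189 and 145. Their clonal folds, which rise where tags stack on few positions, were 0.82, 0.93, 1.57 and 1.33. Cyp26b1 had 0.82 and the Abcg1 peak 0.76, against 0.53 to 0.76 at the 6 peaks called with GW3965 alone. Whether the peaks with many control tags are LXRα sites was not tested.

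Among the 412 shared peaks within 50 kb of a gene and with 50 or more normalised tags in the higher library, the lowest ratios were at peaks in Supt3, Ppp1r12b, Rnf121 and Itsn1 and near Art2b and Fbxo32. They ran from 0.298-fold at Supt3 (53.0 and 15.8 normalised tags, log2 -1.75, -2.28 to -1.26) to 0.388-fold near the muscle atrophy ubiquitin ligase gene Fbxo32 (97.7 and 37.9, log2 -1.37, -1.71 to -1.04). The highest were near Tra2a, in Plekho2, near Otor and Pip4k2a, and in Axl and Rpl26. Axl, a receptor for apoptotic cell uptake, held 37.9 and 58.1 normalised tags (log2 0.62, 0.24 to 0.97), and the ribosomal protein gene Rpl26 50.1 and 76.5 (log2 0.61, 0.29 to 0.93). Plekho2 was 1.76-fold higher with LPS. The peak 7409 bp from Tra2a, at 2.10-fold, was 4.17-fold over input and held 114 control tags.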

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

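All tests in this part were chosen after the result was seen, except those of the input and local requirements and of repeat mapping. The calculations at the 5th percentile, the comparison of folds of matched and unmatched peaks and the median with unmatched peaks counted as lowest were added after the results of these requirements were seen. Outlying libraries were not examined, since each group has 1.

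At strong LXRα peaks the control library held many tags. The 100 highest-scoring GW3965 peaks had a median of 40.8 scaled control tags and the 18 LXR target peaks of score 100 or more a median of 88.4. An even spread at this depth would give 1.99 tags per peak. Open chromatin in the input is argued against as the whole cause, because control tags relative to LXRα tags were 1.66 times (1.15 to 2.09) as high at LXR target peaks as at other peaks of score 100 or more within 1 kb of a gene end (17.7% and 10.7%). Repeated or multi-copy sequence stays open: the median clonal fold of 0.645 (0.58 to 0.79) met the bound of 1 set beforehand, but that bound was wrong because the clonal fold rises where tags stack on few positions, which multi-copy sequence need not cause (4 shared peaks outside the list, just over 4-fold over input with 114 to 424 control tags, had 0.83 to 1.86). Control tags followed LXRα tags across the 18 peaks (Spearman rho 0.945, across peaks, which are not independent replicates), so immunoprecipitated DNA or reads in the control library are another candidate explanation, not separated from the former by this test. No biological explanation was tested, since the labels describe no control library.

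Strong GW3965 peaks often had no counterpart with LPS: 1227 of the 5494 in the highest score decile, against 155 of 4444 in that of GW3965 + LPS. The local requirement is argued against for falls of the size seen at matched peaks, because the unmatched peaks stood as far above it as the matched ones (median 18.2-fold and 17.2-fold over the local region), and 1.71% of the 1227 would come under 4-fold at the median ratio of matched peaks, or 13.6% at the 5th percentile of their ratios. These ratios come only from peaks called in both libraries, so larger falls at the unmatched peaks are not covered. For the input requirement the median ratio gave 15.3%, under the bound of 20% set beforehand, but that bound was wrong in taking the median for every peak: unmatched peaks stood nearer the limit (median 7.27-fold and 10.3-fold over input), and at the 5th percentile (0.411-fold) 80.5% of unmatched and 44.9% of matched peaks would come under it. A general fall in tags at strong peaks stays open. Matched peaks had a median log2 ratio of -0.40 (-0.42 to -0.38). With all 1227 counted as lower than these, the median is -0.57 (-0.59 to -0.55), an interval that includes the first bound of -0.58. A later bound of -1 was not reached, but it rested on a limit of 12 tags for calling a peak and cannot decide. Even at the 5th percentile 0.0% of the unmatched peaks would come under 12 tags, while smaller falls bring peaks under the input limit. The input requirement, a general fall in tags and lower LXRα binding at single sites under LPS cannot be told apart. The lists give no tags where no peak was called.

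The tag ratio at shared peaks depended on distance to gene ends. Among peaks over 15 normalised tags, the median log2 ratio within 1 kb of a gene end exceeded that over 10 kb away by 0.30 (0.26 to 0.34), which argues against a uniformly lower yield of the GW3965 + LPS immunoprecipitation as the whole cause. A lower yield limited to specific LXRα sites, with gene ends holding unspecific signal, would put strong LXR target peaks at or below the distal median of -0.29. The 11 LXR target peaks of 100 tags or more had a median of 0.043 (-0.46 to 0.22), an interval that includes -0.29, so this explanation stays open with so few peaks. These 11 were called in both libraries, so any that fell under 4-fold over input are left out and the median may be too high. LPS treatment itself remains open as a biological explanation and was not tested, because the treatment and the library cannot be separated.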

How the results depend on the processing

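The tests with folds over input of 8 or more, with other tag measures, with distance to gene ends, with the 2.5 kb window and with gene assignment were chosen after the result was seen. Of 105 alternatives for values with an interval or counts, 81 stayed within the interval of the value reported (within 1.5 times for a count) and 24 did not, and for the latter the cause was not tested beyond what each setting removes by construction. GW3965 had more peaks than GW3965 + LPS in each alternative for peak number: 32836 and 24274 at scores of at least 2 times the lowest, and 27798 and 22195 at 8-fold over input. The share of GW3965 peaks overlapped was 49.8% with 50% of both peaks required, 53.9% with centres within 100 bp, 62.1% with lists of equal length, 67.7% for the upper 50% of its list by score and 73.4% for peaks 8-fold over input and local region. The share of GW3965 + LPS peaks was 61.5%, 66.6%, 62.1%, 83.9% and 86.0% in the same order, and equal lengths bring both shares together by construction. The median log2 ratio was -0.15 for the upper 50% of shared peaks by tags, -0.052 with a pseudocount of 5 and -0.16 over 10 kb from a gene end, and it was 0.040 within 1 kb, where equal raw tag counts give 0.038. The share of peaks near a gene end was 26.5% and 32.5% with a 2.5 kb window and 20.7% and 30.5% for the upper 50% by score, higher with LPS in each. Of 48 alternative medians of gene lists 47 stayed within the interval and 42 kept their sign, as did the 4 of the silent lineage list, which has no interval, with NF-kB and inflammatory genes at -0.14 after centring on all shared peaks. Of 26 alternative shares 25 stayed within it, with 12.5% of cholesterol synthesis and uptake peaks in GW3965 alone at equal list lengths. Interferon response genes stayed lower with LPS in all 4 (-0.46 to -0.30). Motif shares were not run for lack of sequence, nor windows and assignments by transcription start for lack of strand. No paired analysis was possible because each group has 1 library. At a median of 28 and 26 tags per peak, ratios of single peaks are imprecise.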

Other observations

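The test of ribosomal protein genes and all genes named in this part were chosen after the result was seen.

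Peak numbers per gene differed in both directions. Of 14293 genes with an assigned peak, 6068 had fewer with GW3965 + LPS, 3351 had more and 4874 had the same number. Lpp, which encodes a focal adhesion protein, had 74 peaks with GW3965 and 35 with GW3965 + LPS. Dock4 had 33 and 14, Creb5 35 and 19, the histone deacetylase gene Hdac9 35 and 19, and Nr3c1, which encodes the glucocorticoid receptor, 23 and 9. In the other direction Mtmr12 had 4 and 11, and Rgs10 and Tspan14 10 and 16 each. Other lipid genes also had strong shared peaks: one in Gramd1b, which encodes a protein that carries cholesterol to the endoplasmic reticulum, held 327 and 326 normalised tags with GW3965 and GW3965 + LPS, and one in the acetyl-CoA carboxylase gene Acaca held more with LPS, 259 and 318 (log2 0.30, 0.15 to 0.44). Shared peaks far from genes on chromosomes 3 and 11, with 849.5 and 780.4 normalised tags in the library with LPS, held 424 and 349.7 control tags.

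Ribosomal protein genes held more ChIP tags with LPS. Their 69 shared peaks within 1 kb of a gene end, at 63 genes, had a median log2 ratio of 0.22 (0.14 to 0.25), and 58 of the 69 were higher with LPS. Rps7 held 242 and 284 normalised tags, Rpl13 186 and 212, Rpl7a 164 and 178, Rpl27 143 and 185, and Rpl32 135 and 137, the intervals for Rpl7a and Rpl32 including no difference. The median lay at percentile 100.0 of 10000 random sets of gene-end peaks matched on tag count, whose median was 0.029. A difference of this gene class from other gene ends is therefore a hypothesis from the same data, and LXRα binding was not separated from unspecific signal at highly transcribed genes.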
